A study of Mus musculus with 105 samples.

How the data were processed

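The libraries are RNA sequencing of total RNA from mouse CD4+ T cells with ERCC spike-ins, 105 libraries in 35 groups of 3 replicates. Per the labels, the authors aligned reads to mm10 with TopHat2 2.0.13 and Bowtie 1.1.1.0 and counted them with HTSeq. The deposited table holds HTSeq read counts, whole numbers with no scaling, for 22322 mouse genes (22124 with a symbol) and 92 ERCC RNAs. It gives counts over exons, over coding sequence, over introns alone and over spike-ins for each library. The labels call the replicates biological, and nothing in them ties a replicate number to a mouse. The series labels also speak of macrophages, but every library in the table is of T cells. Reads left out of gene counts made up 75.84 to 97.25% per library, most of them aligned to more than 1 place (50.52 to 91.48%).

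Exon counts were used for the main results. Genes with enough counts were kept with filterByExpr, which left 10741. All 105 libraries were fitted together as 35 group means with edgeR 4.0.16 (TMM factors, robust quasi-likelihood F test, R 4.3.3), and each comparison is a contrast of group means. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. There are 17 main comparisons among 34 in all. TMM sets the typical gene to no change, so it gives changes relative to the typical mRNA. Scaling on the summed ERCC counts gives changes per spike-in molecule, and cells were collected in equal number at each time point. CPM values use TMM-scaled library sizes, and log2 CPM a prior count of 2. Exon counts per ERCC count were compared with exact permutation tests, two-sided, whose smallest p for 3 against 3 libraries is 0.1. Spearman's rho was computed across genes.

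Gene lists were written before the data were examined and tested with camera (limma 3.58.1) against all other genes, with a preset correlation between genes of 0.01 and again with an estimated correlation, for lists with at least 5 genes tested. List p values were adjusted over all lists of a comparison. Counts adjusted over the list alone repeat the Benjamini-Hochberg step on the members only.

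Genes are named by a rule set before the data were examined. In each comparison these are the 6 largest rises and 6 largest falls among called genes with at least 10 CPM in 1 group and, outside the differences of changes, groups that do not overlap, without predicted, pseudogene and mitochondrial symbols. In each described list the rule names the 2 members with the smallest p and the 2 most abundant. Some genes that the rule selects are not reported here. Il2ra, Cd69 and Myc were fixed as a check of the labels. Genes singled out elsewhere were chosen after their values were seen. Fold changes against a group without counts are given as lower bounds with 3 counts over the group as the floor, and ratios on 1 to 3 counts with a 95% binomial interval. Both cover counting error only. Coordinates are from GENCODE on mm10.

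The libraries with 6300 and 141028 exon counts were kept in the main results and left out in an alternative. On simulated data with 100 genes changed 2-fold and 100 changed 4-fold in an activated triptolide comparison, the procedure recovered 30 and 88 of them, with 7 false calls. In a difference of changes it recovered 10 and 65. With the 6 libraries compared alone it recovered 27 and 84, and DESeq2 1.42.0 recovered 22 and 80. Spike-in scaling returned a planted median of -1 as -1.001. No pair of replicates was found to be a copy of another: among 105 pairs the lowest chi-square per degree of freedom was 3.185 without the 6300-count library and 1.145 with it.

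Alternatives set before the data were examined were DESeq2, RLE factors, library size alone, scaling on mitochondrially encoded mRNAs, no filter, only the libraries compared, the replicate number as a block, each replicate left out in turn, estimated correlation for lists, harringtonine in place of cycloheximide, and only genes with at least 10 CPM. Chosen after seeing the data were scaling on spike-ins without resting 1 h triptolide replicate 3, whose spike-in counts were 660, the replicate number as a block within each cell state, coding-sequence counts, spike-in scaling with replicates left out, sign flips within replicate numbers, and leaving out the 2 shallowest libraries or activated 3 h triptolide replicate 3. The block within each state was added because 103 of 104 libraries lay closest to libraries of their own number in their own state, with a mean correlation of 0.462 against -0.226 for other numbers. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Ribosome density was not analysed here.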

Results

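The data are RNA sequencing counts from mouse CD4+ T cells of C57BL/6J females, taken from spleen and lymph nodes. Activated cells had been stimulated with beads carrying antibodies to CD3 and CD28, and resting cells had not. Total RNA came from the same number of cells at each time point and held ERCC spike-ins, which are synthetic RNAs added in a fixed amount. The libraries form 35 groups of replicates 2, 3 and 4. Of these, 21 are of activated and 14 of resting cells, sampled 0, 1 or 3 h after the inhibitors. Triptolide (25 µM) and DRB (65 µM, activated cells only) block RNA polymerase II. Cycloheximide (100 µg/ml) blocks ribosome elongation and harringtonine (2 µg/ml) blocks the first steps after initiation, alone or with a transcription inhibitor. Exon counts per library ranged from 6300 to 6479221 with a median of 2135800. The shallowest libraries were resting 1 h triptolide replicate 3 (6300) and activated 0 h untreated replicate 3 (141028), and the next held 551975. Changes below are log2 values ± SE with n = 3 libraries per group, levels are depth-scaled counts (CPM) ± SD, and adjusted p values come from edgeR over 10741 genes unless another test is named. A change is relative to the typical mRNA of the libraries compared unless it is called spike-scaled, which gives the change per ERCC molecule.

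The markers of activation, chosen as a check of the labels, were higher in every activated 0 h library than in every resting one. Il2ra stood at 768.2, 246.2 and 382.5 CPM in the activated replicates and at 56.81, 44.86 and 40.08 CPM in the resting ones. Cd69 stood at 2504, 1423 and 1740 CPM against 223.5, 124.9 and 152.4 CPM, and Myc at 526.3, 300.2 and 311.8 CPM against 8.495, 13.87 and 11.45 CPM. Cd4 averaged 202 CPM in activated and 300 CPM in resting cells at 0 h, and Cd8a did not pass 2.297 CPM in any of those 6 libraries.

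The mRNA left after each inhibitor was read from exon counts per ERCC count. Activated cells held 22.7 ± 5.62 (SD, n = 3) exon counts per ERCC count at 0 h of triptolide and 10.0 ± 4.15 after 3 h, or 42.7% as a ratio of geometric means, like each percentage here (exact permutation test, two-sided, p = 0.1). In DRB the ratio went from 20.03 ± 0.499 to 9.14 ± 1.93 (SD, n = 3), or 45%, and in resting cells under triptolide from 18.8 ± 2.91 to 8.11 ± 1.46, or 43% (exact p = 0.1 for both). At 1 h, 64.5%, 70.7% and 62.7% were left in these 3 arms (exact p = 0.1 for each). Cycloheximide added to triptolide left 138% of the level with triptolide alone in activated cells (exact p = 0.4) and 145% in resting cells (exact p = 0.2), and 138% when added to DRB (exact p = 0.1). Harringtonine added to triptolide left 119% in activated (exact p = 0.6) and 126% in resting cells (exact p = 0.3). Without a transcription inhibitor, 3 h of cycloheximide gave 137% of the untreated level in activated and 187% in resting cells, and harringtonine gave 131% and 191% (exact p = 0.1 for each). Activation itself gave 110% at 0 h (exact p = 0.5). The smallest p that 3 against 3 libraries allow is 0.1, so no single one of these comparisons can reach 0.05. Taken by replicate number, all 3 differences were above 0 for each addition in resting cells and for cycloheximide added to DRB (exact sign flips, p = 0.25, the smallest that 3 pairs allow). With cycloheximide or harringtonine added to triptolide in activated cells 2 of 3 were above 0 (exact sign flips, p = 0.5 for both).

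**Figure D1:**
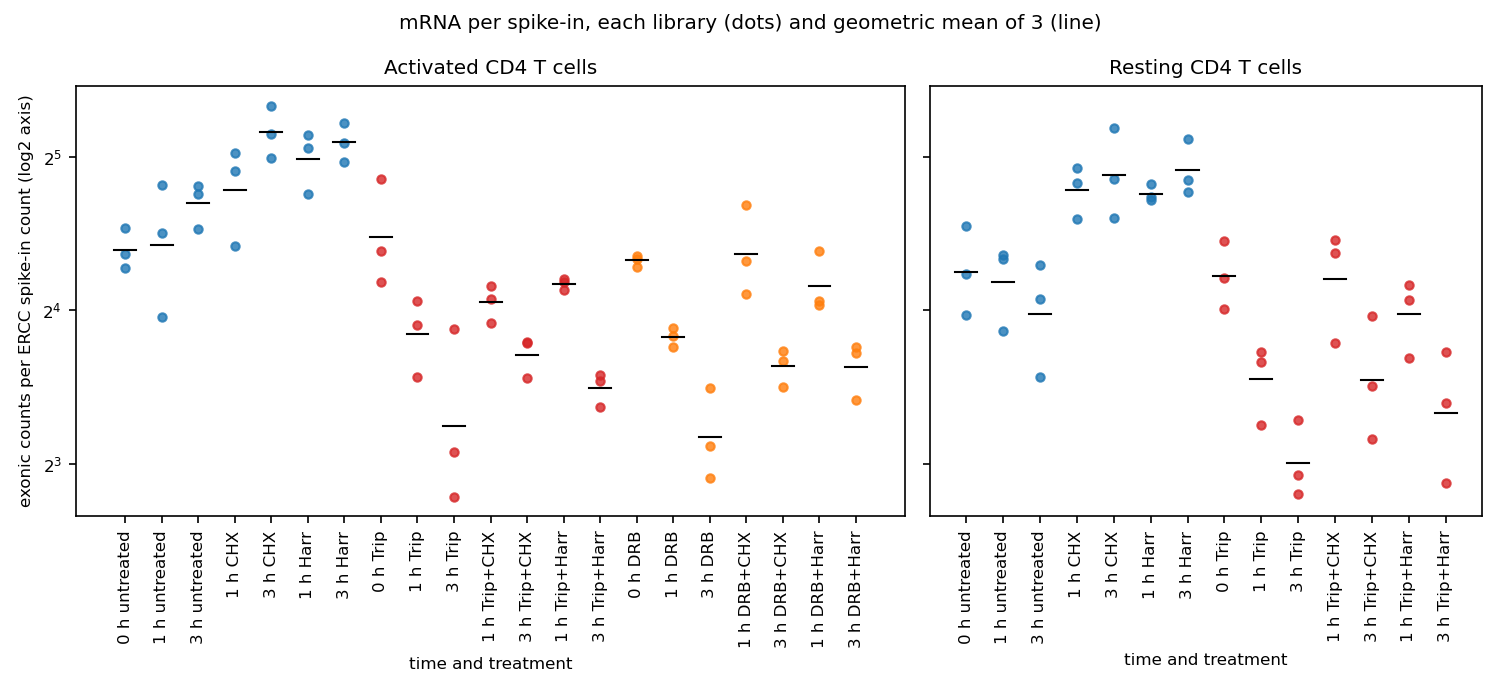
Exon counts per ERCC count (log2 axis) in each library, as points, with the geometric mean of 3 replicates as a line. Triptolide for 3 h left 42.7% of the 0 h level in activated (libraries 6.898 to 14.72) and 43% in resting cells, and DRB 45%.

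Activation, the change that the decay measurements start from, was read from untreated cells at 0 h. T cell receptor and CD28 signals induce immediate early genes within minutes and cytokine genes soon after. Il2 (chromosome 3, 37120523 to 37125959, mm10) rose from 1.12 ± 0.505 to 101 ± 31.8 CPM (SD, n = 3; log2 change 6.38 ± 0.55, adjusted p = 5.92e-16). Egr1 rose by 5.62 ± 0.32, Egr3 by 6.20 ± 0.54 and Pdgfb by 5.34 ± 0.63, and Hivep3 by 6.39 ± 0.95. Ccl4 had no count in the resting libraries and was at least 55-fold higher in activated cells against a floor of 3 counts per group. Genes that fell the most included Kctd12b at −3.07 ± 0.59, Igkv8-24 at −2.78 ± 0.91, Ccdc117 at −2.55 ± 0.34 and Tdrp at −2.52 ± 0.41. The fall of Igkv8-24, an immunoglobulin gene, was not called spike-scaled (adjusted p = 0.0719) or without replicate 2 or 3. Igkc stood at 77.2 CPM in activated and 330 CPM in resting cells, and these levels do not show whether resting libraries hold more B cell RNA.

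Of 28 immediate early genes tested, 19 were higher, 1 lower and 8 not called (21 higher and 1 lower adjusted over the list alone). Their median was 1.89 (camera adjusted p = 2.26e-20, and adjusted p = 0.00374 with an estimated correlation), with Myc at 5.08 ± 0.36 and Nr4a1 at 5.03 ± 0.49. Among 23 cytokine genes 15 were higher, 1 lower and 7 not called (16 and 1 adjusted over the list alone; median 2.45, camera adjusted p = 8.76e-12, adjusted p = 0.000972 with an estimated correlation). Tnfsf11 rose by 3.74 ± 0.27, and Ltb stood at 0.01 ± 0.53. Il16 was lower by 0.74 ± 0.28 (adjusted p = 0.0418), a call kept in 6 of 12 alternatives and lost spike-scaled (adjusted p = 0.389). Among 24 surface and effector markers of activation 15 were higher, 1 lower and 8 not called (16 and 1 adjusted over the list alone; median 1.34, camera adjusted p = 5.87e-13, adjusted p = 0.00338 with an estimated correlation), led by Irf4 at 4.45 ± 0.28. NF-κB feedback genes, a list of NF-κB subunits and other targets of the pathway as well as its inhibitors, were higher in 17 of 19. Adjusted over the list alone 17 were higher and 1 lower, with a median of 1.495 (camera adjusted p = 9.2e-14, adjusted p = 0.00338 with an estimated correlation). Nfkbid rose by 4.14 ± 0.33 and Nfkb1 by 2.18 ± 0.25, and Tnfaip3 was not called at −0.36 ± 0.22.

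The genes of amino-acid synthesis and tRNA charging that ATF4 drives rose almost as a whole, with 23 of 24 higher (24 adjusted over the list alone; median 2.40, camera adjusted p = 5.82e-31, adjusted p = 5.57e-05 with an estimated correlation). Psat1 rose by 3.12 ± 0.25 and Phgdh by 2.54 ± 0.23. Ribosome biogenesis genes were higher in 31 of 34 (31 adjusted over the list alone; median 1.51, camera adjusted p = 1.31e-25, adjusted p = 0.00189 with an estimated correlation), with Polr1b at 2.70 ± 0.26 and Npm1 not called at −0.25 ± 0.19. Naive-state and quiescence genes went the other way, with 14 of 24 lower, 2 higher and 8 not called (14 and 2 adjusted over the list alone; median −0.89, camera adjusted p = 1.56e-05, adjusted p = 0.00673 with an estimated correlation). Klf3 fell by 1.44 ± 0.23, Txnip by 1.70 ± 0.29 and Ets1 by 1.39 ± 0.25, and Btg1 rose by 0.75 ± 0.27. Cytosolic ribosomal protein genes were lower in 27 of 79 (34 adjusted over the list alone; median −0.57, but 0.14 when scaled on mitochondrial mRNAs; camera adjusted p = 1.26e-08, adjusted p = 0.563 with an estimated correlation). Rps4x fell by 1.07 ± 0.25 and Rpsa stood at −0.30 ± 0.28. Replication histone genes were lower in 11 of 50 (10 adjusted over the list alone; median −0.94, camera adjusted p = 0.000183, adjusted p = 0.563 with an estimated correlation), with Hist1h4j at −1.61 ± 0.48.

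In all, 1493 genes were higher and 1382 lower in activated cells. The split was 1709 and 947 in DESeq2, 1826 and 1024 with RLE factors, 4232 and 72 when scaled on mitochondrial mRNAs, and 1149 and 381 on spike-ins, with a median of all genes of 0.76 and 0.18 on these scales. The number called was 1107 without replicate 2 and 1528 without replicate 4.

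Which mRNAs decay faster or slower than the typical one in activated cells was read from triptolide at 3 h against 0 h. Short-lived messages of transcription factors and signalling feedback are the known fast class, and messages for ribosomal proteins and the respiratory chain the slow one. Gadd45gip1 fell from 41.7 ± 16.5 to 3.31 ± 0.817 CPM (SD, n = 3; log2 change −3.61 ± 0.53, adjusted p = 3.66e-08). Tmem115 fell by 3.61 ± 0.53 and Itpripl1 by 3.58 ± 0.58, and Znhit3, with 3 counts left, stood at 0.0536 of its 0 h share (95% counting interval 0.0108 to 0.162). The largest relative rises were in genes with no count at 0 h. Sim1 (chromosome 10, 50894754 to 50989152) reached 128 ± 17.2 CPM, at least 242-fold higher, and Tnn, Kif17, Itgb6, Cgnl1 and Tex13c2 were at least 123, 92.1, 82.9, 62.4 and 63.5-fold higher. Sim1, Tnn, Kif17 and Itgb6 each lie downstream of an expressed gene on the same strand.

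Cytosolic ribosomal protein genes were higher in 76 of 79 (77 adjusted over the list alone; median 1.21, but −0.34 spike-scaled and −0.51 when scaled on mitochondrial mRNAs; camera adjusted p = 3.73e-21, adjusted p = 0.254 with an estimated correlation). Rpl31 rose by 1.53 ± 0.24 relative to the typical mRNA and stood at 0.02 spike-scaled, and Rpsa rose by 1.21 ± 0.28. Mitochondrially encoded mRNAs, which triptolide does not block, were higher in 12 of 13 (12 adjusted over the list alone; median 2.09, and 0.81 spike-scaled but −0.58 without replicate 3; camera adjusted p = 3.55e-06, adjusted p = 0.254 with an estimated correlation), with mt-Co1 at 1.63 ± 0.26. The spike-scaled rise rests on 1 library, activated 3 h triptolide replicate 3, without which it was −0.37 (relative median 1.56). The fast side held 22 of 34 ribosome biogenesis genes, with 1 higher and 11 not called (22 lower and 1 higher adjusted over the list alone; median −0.97, camera adjusted p = 1.67e-06, adjusted p = 0.254 with an estimated correlation). Nop2 fell by 2.03 ± 0.21 and Wdr43 by 1.73 ± 0.18, and Npm1 stood at 0.01 ± 0.19. Proteasome subunits were lower in 23 of 34 (24 adjusted over the list alone; median −0.80, camera adjusted p = 1.77e-05, adjusted p = 0.254 with an estimated correlation), among them Psmc1 at −2.46 ± 0.26 and Psmd12 at −2.80 ± 0.37. NF-κB feedback genes were lower in 14 of 19 (15 adjusted over the list alone; median −1.43, camera adjusted p = 1.09e-05, adjusted p = 0.254 with an estimated correlation), with Nfkbid at −2.35 ± 0.30 and Nfkb1 not called at 0.27 ± 0.24. Of the immediate early genes 15 of 28 were lower (15 adjusted over the list alone; median −1.0, camera adjusted p = 0.00171, adjusted p = 0.357 with an estimated correlation), such as Nr4a1 at −2.62 ± 0.44. Numbered Zfp genes, a family of C2H2 zinc finger proteins, were lower in 108, higher in 14 and not called in 154 of 276 (107 and 14 adjusted over the list alone; median −0.62, camera adjusted p = 0.00454, adjusted p = 0.254 with an estimated correlation). Zfp143 fell by 2.58 ± 0.27 and Zfp407 rose by 1.15 ± 0.33.

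Over all genes 2307 were higher and 2811 lower. Spike-scaled, the median of all genes was −1.67 and the split 214 higher and 8376 lower. It was 193 and 8594 when scaled on mitochondrial mRNAs (median −1.73), 1193 and 4024 by library size, 1517 and 3366 in DESeq2 and 1619 and 3530 with RLE factors.

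DRB, which blocks RNA polymerase II by another route, gave a separate set of libraries. Trib3 fell from 41.0 ± 8.32 to 2.27 ± 3.02 CPM (SD, n = 3; log2 change −4.09 ± 0.57, adjusted p = 2.36e-08) and Irf2bp1 from 58.8 ± 22.2 to 4.15 ± 0.885 CPM (−3.85 ± 0.69). Cyb561d2, with 3 counts left, stood at 0.0579 of its 0 h share (95% counting interval 0.0117 to 0.174). Among genes with no count at 0 h, Foxi1 (chromosome 11, 34204338 to 34208089) rose to 150 ± 97.6 CPM and was at least 404-fold higher, and Apoa1, Olfr1395, Meltf, Cracr2b and Ephx3 were at least 116, 75.4, 61.8, 43.3 and 35.8-fold higher. All 6 lie downstream of an expressed gene on the same strand.

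Ribosomal protein genes were again on the slow side, with 76 of 79 higher (76 adjusted over the list alone; median 1.36, but −0.24 spike-scaled and −0.20 when scaled on mitochondrial mRNAs; camera adjusted p = 5.97e-30, adjusted p = 0.348 with an estimated correlation). Rps24 rose by 1.57 ± 0.23 and Rpl22 by 1.60 ± 0.24. Mitochondrially encoded mRNAs were higher in 11 of 13 (12 adjusted over the list alone; median 1.43, but −0.08 spike-scaled, which was 0.14 and 0.06 without replicates 3 and 4, and −0.10 when scaled on themselves; camera adjusted p = 8.03e-05, adjusted p = 0.357 with an estimated correlation). Replication histone genes were higher in 13 of 50 (12 adjusted over the list alone; median 0.92, but −0.69 spike-scaled and −0.63 on mitochondrial mRNAs; camera adjusted p = 0.000323, adjusted p = 0.558 with an estimated correlation), led by Hist1h4i at 3.59 ± 0.39. Proteasome subunits were lower in 18 of 34 (20 adjusted over the list alone; median −0.63, camera adjusted p = 1.83e-05, adjusted p = 0.348 with an estimated correlation), with Psmc1 at −2.30 ± 0.25. Ribosome biogenesis genes were lower in 17, higher in 1 and not called in 16 of 34 (17 and 1 adjusted over the list alone; median −0.60, camera adjusted p = 0.000243, adjusted p = 0.386 with an estimated correlation), with Nop56 at −2.41 ± 0.22. Of 16 p53 targets 7 were lower (7 adjusted over the list alone; median −0.51, camera adjusted p = 0.0199, adjusted p = 0.205 with an estimated correlation), among them Sesn2 at −2.39 ± 0.27 and Plk3 at −1.88 ± 0.25.

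DRB called 1928 genes higher and 2347 lower, 2347 in all without replicate 4. The split was 157 and 8429 spike-scaled (median of all genes −1.53), 158 and 8386 on mitochondrial mRNAs (median −1.54), 874 and 3934 by library size, 1327 and 2783 in DESeq2 and 1420 and 2943 with RLE factors.

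In resting cells triptolide left an arm of the same kind without receptor signals. Phax fell from 45.7 ± 7.15 to 1.65 ± 0.659 CPM (SD, n = 3; log2 change −4.70 ± 0.52, adjusted p = 5.11e-12). Mrpl16 and Tmem60 had no count left and were at least 11.3-fold and 10.5-fold lower. B3galt6, Zfp85 and Mrpl55 stood at 0.0393, 0.0304 and 0.0307 of their 0 h shares (95% counting intervals 0.00804 to 0.116, 0.000762 to 0.174 and 0.00077 to 0.175). Acot12, Tex13c2, Cacng5 and Cyp26b1 had no count at 0 h and were at least 140, 112, 112 and 87.6-fold higher. Mc5r had no count at 0 h either and a larger such minimum than Cyp26b1, and Foxi1 was 636-fold higher (95% counting interval 217 to 3090). Acot12, Cacng5, Mc5r, Cyp26b1 and Foxi1 each lie downstream of an expressed gene on the same strand.

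Ribosomal protein genes were higher in 77 of 79 (78 adjusted over the list alone; median 1.43, but −0.25 spike-scaled; camera adjusted p = 2.37e-22, adjusted p = 0.233 with an estimated correlation), with Fau at 1.79 ± 0.22. Mitochondrially encoded mRNAs were higher in 11 of 13 (12 adjusted over the list alone; median 1.18, but −0.58 spike-scaled and −0.01 when scaled on themselves; camera adjusted p = 0.00901, adjusted p = 0.437 with an estimated correlation). Proteasome subunits were lower in 29 of 34 (30 adjusted over the list alone; median −1.25, camera adjusted p = 2.63e-08, adjusted p = 0.199 with an estimated correlation), with Psmc1 at −3.41 ± 0.31 and Psmb7 at −2.65 ± 0.26, while Psmb1 and Psmd4 were not called. Ribosome biogenesis genes were lower in 22 of 34 (22 adjusted over the list alone; median −1.33, camera adjusted p = 0.00033, adjusted p = 0.315 with an estimated correlation). Of 24 activation markers, 15 were lower, 1 higher and 8 not called (16 and 1 adjusted over the list alone; median −1.71, camera adjusted p = 0.00089, adjusted p = 0.233 with an estimated correlation), such as Tnfrsf4 at −2.54 ± 0.25 and Pdcd1 at −2.86 ± 0.33. Heat shock chaperones were lower in 11, higher in 1 and not called in 7 of 19 (12 and 1 adjusted over the list alone; median −0.88, camera adjusted p = 0.00192, adjusted p = 0.199 with an estimated correlation), with Dnajb1 at −3.07 ± 0.37 and Hspa8 at −1.31 ± 0.26. In resting cells left without inhibitor for 3 h, 7 of 24 activation markers (median −0.76), 7 of 19 heat shock chaperones (median −0.40) and 6 of 34 ribosome biogenesis genes (median −0.55, with 1 higher) were lower too. Without replicate 4 these lower calls were 2, 1 and 0, spike-scaled 1, 2 and 1, and there were 0 on mitochondrial mRNAs, with the medians below 0 in both. Whether triptolide adds to this change in these lists was not tested. Cholesterol synthesis genes were lower in 13 of 23 (13 adjusted over the list alone; median −1.01, camera adjusted p = 0.00405, adjusted p = 0.199 with an estimated correlation), with Insig1 at −2.31 ± 0.26.

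Triptolide gave 2852 genes higher and 3252 lower in resting cells, where 3 h without inhibitor gave 325 and 361 (114 called without replicate 4, 30 higher and 146 lower spike-scaled, and 71 and 51 on mitochondrial mRNAs). The split was 216 and 8149 spike-scaled (median of all genes −1.75), 356 and 6409 on mitochondrial mRNAs (median −1.25), 1525 and 4691 by library size, 2050 and 3780 in DESeq2 and 2121 and 3928 with RLE factors.

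**Figure D2:**
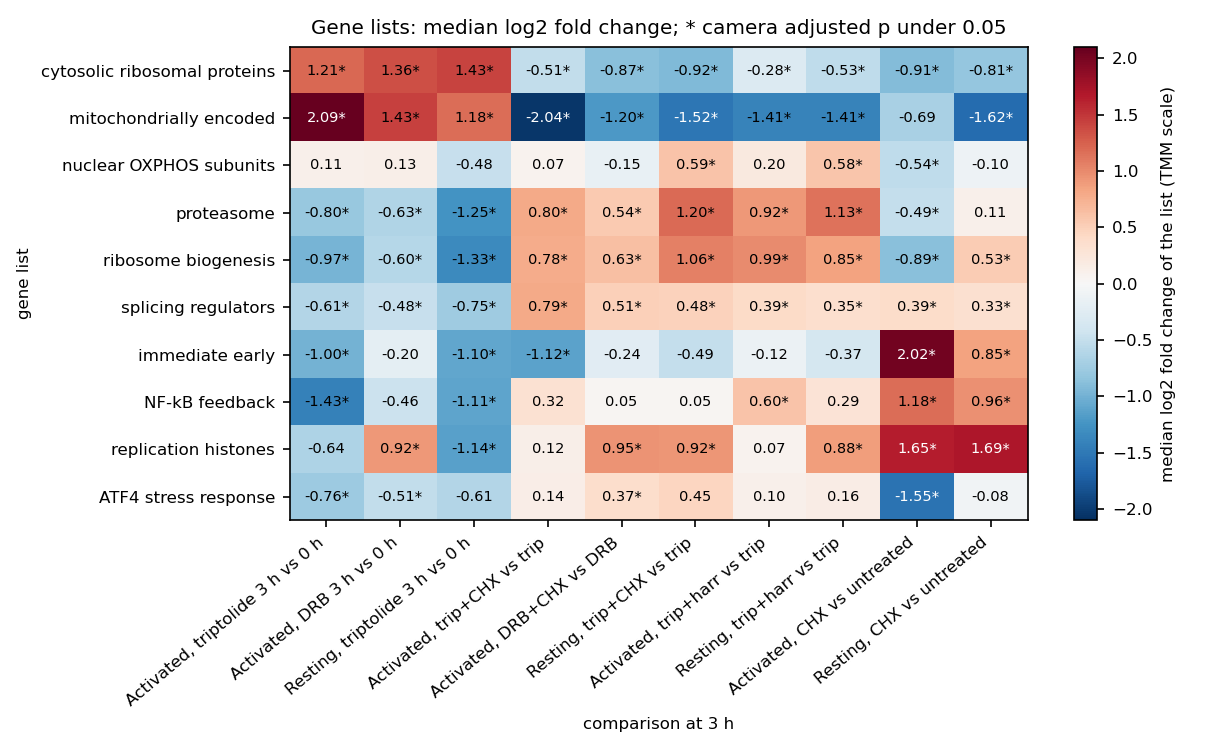
Median log2 change of 10 gene lists (rows) in 10 comparisons (columns), relative to the typical mRNA, with * for a camera adjusted p under 0.05. Ribosomal protein genes stood at 1.21, 1.36 and 1.43 after triptolide or DRB, which turn to −0.34, −0.24 and −0.25 spike-scaled, and at −0.51, −0.87 and −0.92 when cycloheximide was added, which turn to 0.12, −0.07 and −0.02.

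**Figure D3:**
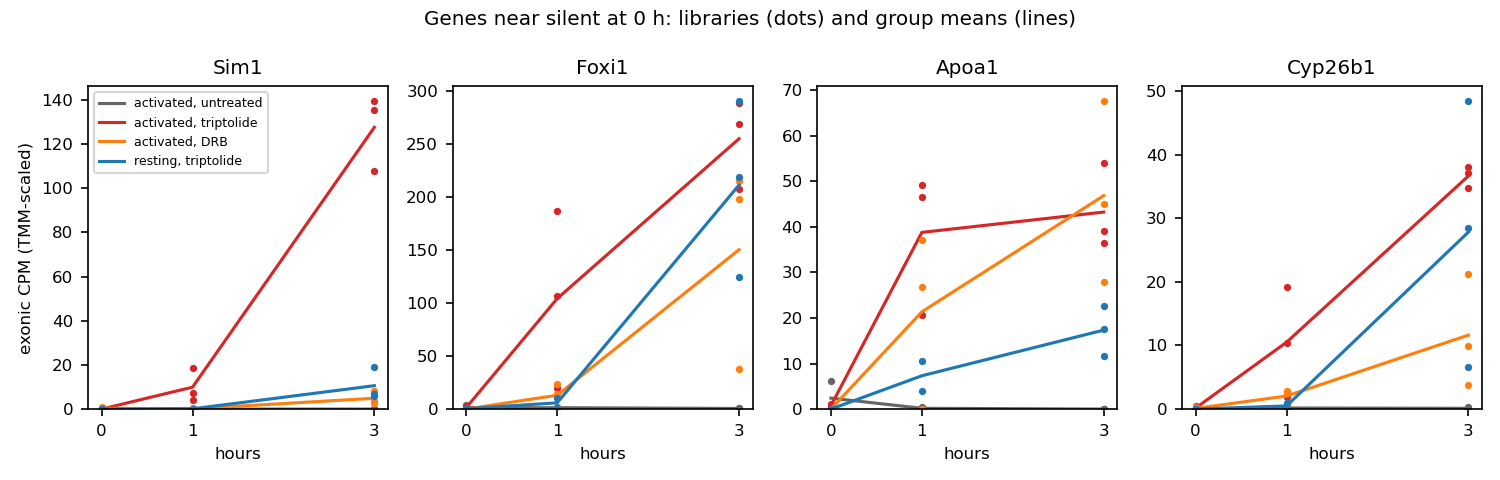
CPM of Sim1, Foxi1, Apoa1 and Cyp26b1 (linear axis) against hours, for activated cells untreated or in triptolide or DRB and resting cells in triptolide. Libraries are points and group means lines, without resting 1 h triptolide replicate 3. Sim1 reached 128 CPM after 3 h of triptolide in activated cells and Foxi1 reached 150 CPM after 3 h of DRB, each from no count at 0 h of the same inhibitor.

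Whether decay differs with activation was tested as the difference of the 3 h triptolide changes, activated minus resting. Tfrc decayed less in activated cells, with a difference of 1.76 ± 0.34 (adjusted p = 0.000439). It went from 380 ± 31.2 to 782 ± 207 CPM (SD, n = 3) in activated and from 93.4 ± 25.1 to 57.0 ± 9.23 CPM in resting cells. Uqcrb differed by 2.55 ± 0.52 (adjusted p = 0.000632) and Psma2 by 1.91 ± 0.37 (adjusted p = 0.000427). Other large differences show gains, not slower decay. P2ry1 (3.73 ± 0.94, 0.724 to 30.3 CPM) and Cpne2 (3.81 ± 1.16) rose in activated cells. Slc7a3 (−2.98 ± 0.70), Evi5 (−2.67 ± 0.60, 3.15 to 119 CPM) and Ust (−2.37 ± 0.48) rose more in resting cells.

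Nuclear genes of oxidative phosphorylation had a higher change in activated cells in 9 of 73 (12 adjusted over the list alone; median 0.58, camera adjusted p = 1.64e-06, adjusted p = 0.863 with an estimated correlation), with Cycs at 1.62 ± 0.37. Proteasome subunits were higher in 5 of 34 and lower in 1 (10 and 1 adjusted over the list alone; median 0.63, camera adjusted p = 0.00117, adjusted p = 0.863 with an estimated correlation), with Psmb2 at 1.60 ± 0.31 and Psmd4 at −1.10 ± 0.34. Activation markers were higher in 3 of 24 (4 adjusted over the list alone; median 0.56, but −0.02 when scaled on mitochondrial mRNAs; camera adjusted p = 0.0196, adjusted p = 0.863 with an estimated correlation), among them Tnfrsf18 at 1.12 ± 0.35. In all, 437 genes had a higher and 258 a lower change in activated cells. The split was 583 and 138 by library size, 16 and 89 on mitochondrial mRNAs and 191 and 17 spike-scaled, and 227 were called without replicate 2 and 146 without replicate 4.

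Whether the transcription inhibitors give the same decay was tested as triptolide minus DRB in activated cells. Replication histone messages were among the largest differences. Hist1h4i went from 5.30 ± 4.31 to 3.08 ± 1.19 CPM (SD, n = 3) in triptolide and from 5.39 ± 0.997 to 69.7 ± 40.6 CPM in DRB, a difference of −4.31 ± 0.71 (adjusted p = 1.94e-05). Hist1h1c differed by −3.27 ± 0.58. Nfkbiz stood at 135 ± 12.2 and 117 ± 15.9 CPM in triptolide and reached 784 ± 258 CPM from 170 ± 21.9 in DRB, a difference of −2.41 ± 0.37 (adjusted p = 5.54e-06). P4htm (−6.43 ± 1.07) and Aph1c (−4.91 ± 1.00) reached 91.7 and 90.5 CPM in DRB from 2.28 and 1.53. As with Hist1h4i, these are gains, not decay. Cyp7a1 went from no count to 30.3 ± 13.1 CPM in 3 h of triptolide and had none after 3 h of DRB.

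Among replication histone genes 7 of 50 had a lower change in triptolide (17 adjusted over the list alone; median −1.32, camera adjusted p = 2.37e-16, adjusted p = 0.217 with an estimated correlation). NF-κB feedback genes were lower in 4 of 19 (8 adjusted over the list alone; median −0.88, camera adjusted p = 1.82e-14, adjusted p = 0.011 with an estimated correlation), with Tnfaip3 at −1.88 ± 0.31 and Nfkbid at −1.89 ± 0.41. Immediate early genes were lower in 5 of 28 (5 adjusted over the list alone; median −0.88, camera adjusted p = 1.22e-06, adjusted p = 0.341 with an estimated correlation), with Dusp5 at −1.99 ± 0.45 and Ppp1r15a at −1.64 ± 0.39. Over all genes 36 had a higher and 112 a lower change in triptolide, 148 in all, against 70 without replicate 2 and 31 without replicate 4. The split was 15 and 48 spike-scaled and 14 and 56 on mitochondrial mRNAs, and with only the libraries compared 53 were called.

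What translation removes was read by adding cycloheximide to triptolide for 3 h: a message that needs ribosomes to decay is then kept. In activated cells Plrg1 rose from 6.57 ± 3.15 to 86.4 ± 14.5 CPM (SD, n = 3; log2 change 3.53 ± 0.38, adjusted p = 7.33e-12) and Nufip1 from 5.54 ± 2.00 to 58.7 ± 14.1 CPM (3.27 ± 0.34). Gemin5 rose by 2.79 ± 0.23, Pdcd2 by 3.2 ± 0.42 and Ngdn by 2.99 ± 0.36. Among the largest falls were Tnf at −2.22 ± 0.40, Lif at −2.28 ± 0.45 and Zfp36 at −2.31 ± 0.42.

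Proteasome subunits were higher in 23 of 34 (27 adjusted over the list alone; median 0.80, camera adjusted p = 2.44e-09, adjusted p = 0.239 with an estimated correlation), with Psmb10 at 2.05 ± 0.30 and Psmd12 at 2.48 ± 0.37. Ribosome biogenesis genes were higher in 20 of 34 (21 higher and 1 lower adjusted over the list alone; median 0.78, camera adjusted p = 3.24e-09, adjusted p = 0.258 with an estimated correlation), with Nop56 at 2.30 ± 0.22 and Wdr43 at 1.89 ± 0.18. SR and other splicing genes with poison exons, whose unproductive isoforms are removed by nonsense-mediated decay, were higher in 10, lower in 1 and not called in 10 of 21 (11 and 1 adjusted over the list alone; median 0.79, camera adjusted p = 0.000654, adjusted p = 0.268 with an estimated correlation), with Srsf7 at 1.65 ± 0.21. Immediate early genes were lower in 14 of 28 (15 adjusted over the list alone; median −1.12, but 0.21 when scaled on mitochondrial mRNAs; camera adjusted p = 5.25e-06, adjusted p = 0.384 with an estimated correlation), with Btg2 at −1.86 ± 0.26 and Egr1 at −1.81 ± 0.28. Mitochondrially encoded mRNAs were lower in 12 of 13 (12 adjusted over the list alone; median −2.04, camera adjusted p = 1.03e-07, adjusted p = 0.268 with an estimated correlation), with mt-Nd1 at −2.13 ± 0.36 and a median of −1.21 without replicate 3. Spike-scaled the median of all replicates was −1.68, and −0.44 without activated 3 h triptolide replicate 3. Ribosomal protein genes were lower in 19 of 79 (18 adjusted over the list alone; median −0.51, but 0.12 spike-scaled and 0.85 on mitochondrial mRNAs; camera adjusted p = 2e-08, adjusted p = 0.669 with an estimated correlation).

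Cycloheximide called 1697 genes higher and 1239 lower in this arm. The split was 3690 and 37 spike-scaled (median of all genes 0.61), 7172 and 6 on mitochondrial mRNAs (median 1.24) and 2290 and 518 by library size. The number called was 4518 with the replicate number as a block within each cell state and 1261 without replicate 4.

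With DRB in place of triptolide, Ngdn rose from 6.70 ± 2.43 to 65.4 ± 22.2 CPM (SD, n = 3; log2 change 3.25 ± 0.38, adjusted p = 4.61e-10) and Trib3 by 3.05 ± 0.64. Zfp157 rose by 3.14 ± 0.50 and Rps19bp1 by 2.99 ± 0.59, and Cyb561d2, from 3 counts, was 11.8-fold higher (95% counting interval 3.69 to 59.9). Xcl1, the chemokine lymphotactin, fell by 1.79 ± 0.55 and Rps27l by 1.87 ± 0.43.

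The ribosome biogenesis list was higher in 14 of 34 (16 adjusted over the list alone; median 0.63, camera adjusted p = 1.07e-07, adjusted p = 0.408 with an estimated correlation), led by Nop56 at 2.61 ± 0.23. Proteasome subunits were also higher in 14 of 34 (17 adjusted over the list alone; median 0.54, camera adjusted p = 2.24e-07, adjusted p = 0.408 with an estimated correlation). Replication histone genes were higher in 13 of 50 (17 adjusted over the list alone; median 0.95, camera adjusted p = 4.69e-07, adjusted p = 0.582 with an estimated correlation), with Hist1h4b at 1.73 ± 0.41. ATF4-driven genes were higher in 5 of 24 (5 adjusted over the list alone; median 0.37, camera adjusted p = 0.00878, adjusted p = 0.582 with an estimated correlation), with Sesn2 at 2.14 ± 0.28 and Sars at 0.98 ± 0.18. Ribosomal protein genes were lower in 54 of 79 (70 adjusted over the list alone; median −0.87, but 0.29 when scaled on mitochondrial mRNAs; camera adjusted p = 1.08e-22, adjusted p = 0.408 with an estimated correlation), with Rpl14 at −1.51 ± 0.24. Over all genes 1126 were higher and 767 lower. The split was 3161 and 12 spike-scaled (median of all genes 0.59), 5959 and 7 on mitochondrial mRNAs (median 1.03), 1987 and 227 by library size, 1232 and 499 in DESeq2, 1282 and 546 with RLE factors and 417 and 42 with only the libraries compared. The number called was 3443 with the replicate number as a block within each cell state, 1103 without replicate 2 and 572 without replicate 4.

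In resting cells cycloheximide on top of triptolide kept Zfp746, which rose from 11.7 ± 2.86 to 111 ± 20.1 CPM (SD, n = 3; log2 change 3.22 ± 0.36, adjusted p = 3.42e-11). Rrp8 rose by 3.35 ± 0.42, Phax by 3.05 ± 0.60 and Mrpl36 by 3.22 ± 0.60, and Cox20, from 3 counts, was 10.4-fold higher (95% counting interval 3.39 to 51.5). Usp46 fell by 2.30 ± 0.41, Prdm14 by 2.40 ± 0.58, Gsdmc3 by 2.49 ± 0.58 and Nipal4 by 2.45 ± 0.69.

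Proteasome subunits were higher in 28 of 34 (31 adjusted over the list alone; median 1.20, camera adjusted p = 1.34e-15, adjusted p = 0.0272 with an estimated correlation), with Psmb2 at 2.08 ± 0.24 and Psma2 at 2.19 ± 0.28. Ribosome biogenesis genes were higher in 19 of 34 (20 adjusted over the list alone; median 1.06, camera adjusted p = 1.53e-07, adjusted p = 0.455 with an estimated correlation), with Nop2 at 2.32 ± 0.25. Nuclear genes of oxidative phosphorylation were higher in 31, lower in 3 and not called in 39 of 73 (33 and 3 adjusted over the list alone; median 0.59, camera adjusted p = 9.99e-05, adjusted p = 0.749 with an estimated correlation), with Uqcrc2 at 1.78 ± 0.20 and Ndufa9 at 1.84 ± 0.22. Ribosomal protein genes were lower in 70 of 79 (75 adjusted over the list alone; median −0.92, but 0.46 when scaled on mitochondrial mRNAs; camera adjusted p = 5.71e-19, adjusted p = 0.473 with an estimated correlation). Mitochondrially encoded mRNAs were lower in 12 of 13 (12 adjusted over the list alone; median −1.53, camera adjusted p = 7.09e-06, adjusted p = 0.455 with an estimated correlation). In all, 2020 genes were higher and 1758 lower. The split was 4925 and 19 spike-scaled (median of all genes 0.86), 7077 and 5 on mitochondrial mRNAs (median 1.32) and 3121 and 567 by library size, and 1737 genes were called without replicate 4.

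The cycloheximide effect itself was compared between states as activated minus resting under triptolide. Nfkbid (NF-κB inhibitor delta) was kept in activated cells, from 282 ± 87.9 to 868 ± 139 CPM (SD, n = 3), and not in resting cells, from 48.7 ± 6.60 to 20.7 ± 3.94 CPM, a difference of 2.88 ± 0.46 (adjusted p = 7.37e-05). Gfi1 differed by 1.61 ± 0.39, Slc25a25 by 1.74 ± 0.37 and Naca by 1.37 ± 0.30. Psmb2 was kept more in resting cells, with a difference of −1.62 ± 0.31 (adjusted p = 0.00236), as were Ranbp1 at −1.84 ± 0.38 and Ndufc1 at −2.08 ± 0.45.

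Messages with a 5′ TOP motif other than those for ribosomal proteins had a higher effect in 1 of 23 (3 adjusted over the list alone; median 0.29, camera adjusted p = 8.95e-06, adjusted p = 0.675 with an estimated correlation). Proteasome subunits had a lower one in 1 of 34 (8 adjusted over the list alone; median −0.50, camera adjusted p = 3.62e-05, adjusted p = 0.798 with an estimated correlation). Of 73 nuclear genes of oxidative phosphorylation, edgeR called none over all genes and 2 lower adjusted over the list alone, with 16 lower at an unadjusted p under 0.05 and 0 called by DESeq2. Their median was −0.48 (camera adjusted p = 6.18e-08, adjusted p = 0.798 with an estimated correlation). Over all genes 11 had a higher and 20 a lower effect in activated cells. The split was 11 and 33 with RLE factors and 12 and 110 by library size, 1 gene was higher on mitochondrial mRNAs, and edgeR called 0 spike-scaled, with 724 at an unadjusted p under 0.05 and 53 called by DESeq2 with its own size factors. Without replicate 2 the number called was 20, and without replicate 4 it was 1. With the replicate number as a block it was 104, and as a block within each cell state 314, 89 higher and 225 lower.

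Harringtonine, which lets elongating ribosomes run off, blocks translation in another mode. Under triptolide in activated cells Pdcd2 rose from 2.96 ± 1.65 to 51.5 ± 10.8 CPM (SD, n = 3; log2 change 4.03 ± 0.41, adjusted p = 3.41e-13), and Mphosph10 by 3.38 ± 0.33, Gadd45gip1 by 3.43 ± 0.54, Nufip1 by 3.44 ± 0.35, Plrg1 by 3.39 ± 0.38 and Ngdn by 3.35 ± 0.36. Rpn1 fell from 126 ± 19.1 to 8.87 ± 3.53 CPM (−3.82 ± 0.33, adjusted p = 7.71e-16), Pgam1 by 2.66 ± 0.22, Psma5 by 2.69 ± 0.34 and Tgfb1 by 2.51 ± 0.45. The ribosome biogenesis list was higher in 21 of 34 (22 adjusted over the list alone; median 1.00, camera adjusted p = 1.95e-14, adjusted p = 0.0814 with an estimated correlation). Proteasome subunits were higher in 22, lower in 4 and not called in 8 of 34 (24 and 4 adjusted over the list alone; median 0.92, camera adjusted p = 2.1e-07, adjusted p = 0.306 with an estimated correlation), with Psma7 at 1.65 ± 0.22. NF-κB feedback genes were higher in 6 of 19 (6 adjusted over the list alone; median 0.60, camera adjusted p = 0.0224, adjusted p = 0.612 with an estimated correlation), with Rela at 1.46 ± 0.25. Mitochondrially encoded mRNAs were lower in 10 of 13 (11 adjusted over the list alone; median −1.41, and −0.86 without activated 3 h triptolide replicate 3, which spike-scaled were −1.31 and −0.16; camera adjusted p = 0.000172, adjusted p = 0.578 with an estimated correlation). In all, 1593 genes were higher and 1057 lower. The split was 2303 and 122 spike-scaled (median of all genes 0.37), 4858 and 28 on mitochondrial mRNAs (median 0.89) and 2021 and 586 by library size, and 1318 genes were called without replicate 4.

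Harringtonine in resting cells raised Aimp2 from 1.65 ± 0.659 to 22.6 ± 7.51 CPM (SD, n = 3; log2 change 3.68 ± 0.47, adjusted p = 1.76e-09), Pttg1 by 3.35 ± 0.45, Mphosph10 by 3.27 ± 0.46 and Zfp746 by 3.05 ± 0.36. Ccni fell from 626 ± 51.9 to 151 ± 18.4 CPM (−2.06 ± 0.17, adjusted p = 1.85e-16). Proteasome subunits were higher in 24, lower in 1 and not called in 9 of 34 (26 and 1 adjusted over the list alone; median 1.13, camera adjusted p = 5.15e-15, adjusted p = 0.0304 with an estimated correlation), with Psmb2 at 2.46 ± 0.24. Of 34 ribosome biogenesis genes 15 were higher (18 adjusted over the list alone; median 0.85, camera adjusted p = 4.69e-09, adjusted p = 0.26 with an estimated correlation). Nuclear genes of oxidative phosphorylation were higher in 31 and lower in 1 of 73 (34 and 1 adjusted over the list alone; median 0.58, camera adjusted p = 3.23e-07, adjusted p = 0.564 with an estimated correlation), with Ndufa9 at 2.04 ± 0.22. Cell cycle genes were higher in 8, lower in 1 and not called in 22 of 31 (8 and 1 adjusted over the list alone; median 0.51, camera adjusted p = 0.0141, adjusted p = 0.321 with an estimated correlation), with Mcm7 at 1.73 ± 0.21 and Mcm6 at 1.72 ± 0.24. Over all genes 1566 were higher and 1014 lower. The split was 2865 and 20 spike-scaled (median of all genes 0.50), 5487 and 4 on mitochondrial mRNAs (median 0.99) and 2168 and 337 by library size. The number called was 4056 with the replicate number as a block within each cell state, 1714 without replicate 3 and 1060 without replicate 4.

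The translation inhibitors were also set against each other under triptolide. In activated cells Rpn1 (chromosome 6, 88084482 to 88105304), for a subunit of the oligosaccharyltransferase, stood at 91.2 ± 12.5 CPM with cycloheximide and 8.87 ± 3.53 CPM with harringtonine (SD, n = 3; log2 difference 3.36 ± 0.33, adjusted p = 2.57e-12). Uqcrc1 was higher with cycloheximide by 2.20 ± 0.26, Selplg by 2.43 ± 0.39 and Psma5 by 2.34 ± 0.33, and Trbv5, with 3 counts in harringtonine, was 18.7-fold higher (95% counting interval 6.21 to 92.3). Gadd45gip1 was lower with cycloheximide at −2.74 ± 0.43, as were Tnf at −2.25 ± 0.38 and Zfp36 at −2.06 ± 0.41. In resting cells Rpn1 differed by 2.73 ± 0.31, Vamp8 by 2.25 ± 0.40, Psma5 by 2.09 ± 0.30 and Uqcrc1 by 1.84 ± 0.25, and Gadd45gip1 by −2.33 ± 0.43.

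Immediate early genes were lower with cycloheximide in 8 of 28 in activated cells (12 adjusted over the list alone; median −0.74, camera adjusted p = 4.43e-09, adjusted p = 0.343 with an estimated correlation), with Egr1 at −1.93 ± 0.28 and Btg2 at −1.85 ± 0.26. T cell identity genes were higher in 3 of 25 (5 adjusted over the list alone; median 0.27, camera adjusted p = 0.00128, adjusted p = 0.276 with an estimated correlation), with Lck at 0.91 ± 0.16 and Thy1 at 1.18 ± 0.28, and in resting cells in 1 of 25, Cd27 at 0.89 ± 0.22 (4 adjusted over the list alone; median 0.16, camera adjusted p = 0.026, adjusted p = 0.748 with an estimated correlation). Cholesterol synthesis genes were higher with cycloheximide in 4 of 23 in activated cells (6 adjusted over the list alone; median 0.27, camera adjusted p = 0.0124, adjusted p = 0.396 with an estimated correlation), with Insig1 at 1.23 ± 0.24. In resting cells edgeR called none of 79 ribosomal protein genes over all genes or adjusted over the list alone, with 7 lower at an unadjusted p under 0.05 and 0 called by DESeq2, while their median was −0.37 (camera adjusted p = 6.35e-12, adjusted p = 0.748 with an estimated correlation).

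In activated cells 364 genes were higher and 160 lower with cycloheximide. The split was 451 and 17 on mitochondrial mRNAs and 329 and 23 spike-scaled, with a median of all genes of 0.30 and 0.19 on these scales. The number called was 1216 with the replicate number as a block within each cell state, 303 without replicate 2 and 87 without replicate 4. In resting cells 214 were higher and 19 lower. The split there was 305 and 1 spike-scaled (median of all genes 0.27) and 192 and 1 on mitochondrial mRNAs (median 0.24). The number called there was 676 with that block, and 92, 136 and 44 without replicates 2, 3 and 4. Both states shared 143 genes higher with cycloheximide, where independent lists of these sizes share 7.25.

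**Figure D4:**
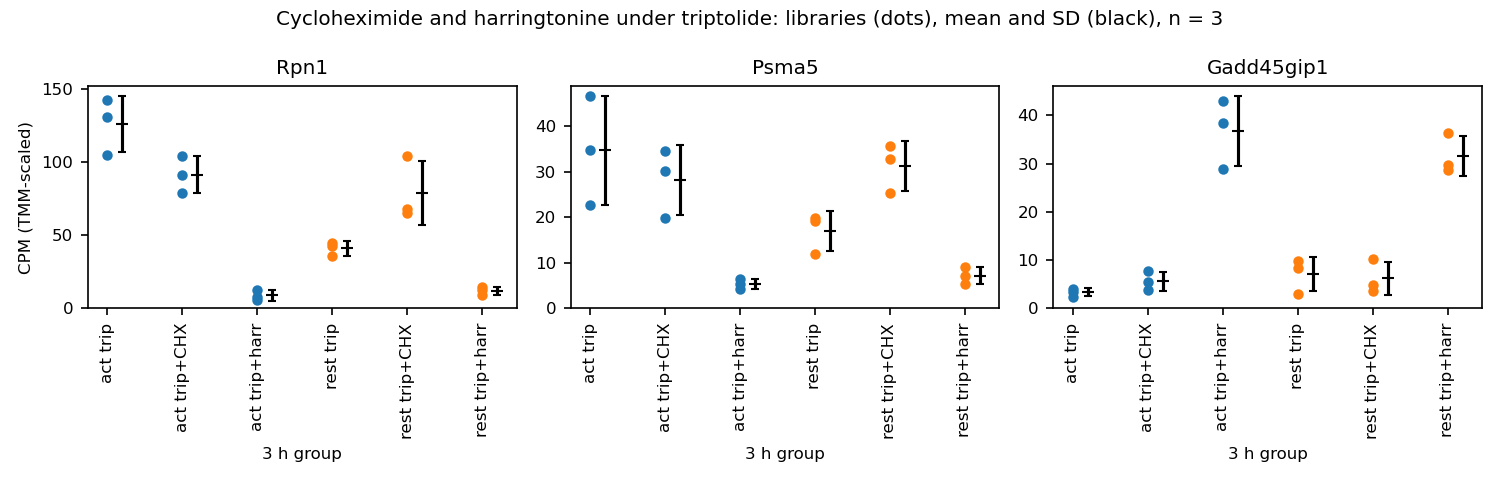
CPM (linear axis) of Rpn1, Psma5 and Gadd45gip1 at 3 h with triptolide, and with triptolide plus cycloheximide or harringtonine, in activated and resting cells, as libraries with the mean and SD (n = 3). Rpn1 stood at 91.2 CPM with cycloheximide and 8.87 CPM with harringtonine in activated cells, and Gadd45gip1 at 5.65 and 36.8 CPM.

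Cycloheximide without a transcription inhibitor shows what a translation block does while genes are still being made. Superinduction of immediate early genes is the textbook response. In activated cells Fos rose from 44.5 ± 7.75 to 628 ± 66.1 CPM (SD, n = 3; log2 change 3.83 ± 0.36, adjusted p = 8.4e-14), Egr1 by 3.69 ± 0.28, Dusp8 by 5.01 ± 0.36 and Areg by 3.92 ± 0.40. Zfp36, which fell when cycloheximide was added to triptolide, rose here by 3.65 ± 0.31. Slc7a11 fell by 3.03 ± 0.43 and Sqle by 2.77 ± 0.32. Immediate early genes were higher in 22 of 28 (25 adjusted over the list alone; median 2.02, camera adjusted p = 1.12e-20, adjusted p = 0.00727 with an estimated correlation), with Junb at 2.78 ± 0.49. NF-κB feedback genes were higher in 13 of 19 (13 higher and 1 lower adjusted over the list alone; median 1.18, camera adjusted p = 2.16e-12, adjusted p = 0.00791 with an estimated correlation), with Nfkbiz at 2.81 ± 0.27. Replication histone genes were higher in 39, lower in 1 and not called in 10 of 50 (41 and 1 adjusted over the list alone; median 1.65, camera adjusted p = 2.92e-11, adjusted p = 0.172 with an estimated correlation), with Hist1h4c at 2.53 ± 0.35. ATF4-driven genes were lower in 21 of 24 (21 lower and 1 higher adjusted over the list alone; median −1.55, camera adjusted p = 3.47e-16, adjusted p = 0.00727 with an estimated correlation), with Psat1 at −1.92 ± 0.22 and Atf4 itself not called at 0.23 ± 0.26. Cholesterol synthesis genes were lower in 15 of 23 (15 adjusted over the list alone; median −0.93, camera adjusted p = 5.85e-08, adjusted p = 0.00727 with an estimated correlation). Glycolysis genes were lower in 11, higher in 1 and not called in 7 of 19 (11 and 1 adjusted over the list alone; median −0.84, camera adjusted p = 7.57e-06, adjusted p = 0.0305 with an estimated correlation), with Slc16a1 at −2.46 ± 0.21. In all, 1616 genes were higher and 1609 lower. The split was 2691 and 297 spike-scaled (median of all genes 0.46) and 3602 and 187 on mitochondrial mRNAs (median 0.65), and 1566 genes were called without replicate 4.

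Resting cells under cycloheximide alone raised Dusp8 by 3.40 ± 0.42, Ccr8 by 2.50 ± 0.38 and Atf3 by 2.47 ± 0.42, and Tnfaip3 rose from 654 ± 54.9 to 2640 ± 211 CPM (SD, n = 3; log2 change 2.01 ± 0.22, adjusted p = 1.28e-10). Cpeb2 fell by 2.53 ± 0.29 and Idh1 by 2.47 ± 0.43. Replication histone genes were higher in 40 of 50 (47 adjusted over the list alone; median 1.69, camera adjusted p = 1.5e-15, adjusted p = 0.197 with an estimated correlation), with Hist1h4d at 2.15 ± 0.31. NF-κB feedback genes were higher in 11 of 19 (13 adjusted over the list alone; median 0.97, camera adjusted p = 2.39e-08, adjusted p = 0.0715 with an estimated correlation). Immediate early genes were higher in 14 of 28 (14 adjusted over the list alone; median 0.85, camera adjusted p = 2.75e-07, adjusted p = 0.219 with an estimated correlation), with Gadd45b at 2.39 ± 0.29 and Jun at 2.15 ± 0.30. Factors of nonsense-mediated decay and its known targets were higher in 10, lower in 2 and not called in 5 of 17 (10 and 2 adjusted over the list alone; median 0.66, camera adjusted p = 0.00113, adjusted p = 0.0488 with an estimated correlation), with Atf4 at 1.60 ± 0.27 and Smg1 at −0.80 ± 0.22. All 13 mitochondrially encoded mRNAs were lower (13 adjusted over the list alone; median −1.62, camera adjusted p = 2.39e-08, adjusted p = 0.177 with an estimated correlation), with mt-Co1 at −1.53 ± 0.26. In all, 1483 genes were higher and 1341 lower. The split was 6563 and 32 spike-scaled (median of all genes 1.01), 8858 and 7 on mitochondrial mRNAs (median 1.56), 2073 and 934 by library size, 1999 and 863 in DESeq2 and 2095 and 914 with RLE factors. The number called was 4706 with the replicate number as a block within each cell state and 884 without replicate 4.

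The background of the activated time courses is the change in cells left without inhibitor for 3 h. Il7r, the receptor of naive T cells, fell from 205 ± 68.8 to 22.2 ± 3.85 CPM (SD, n = 3; log2 change −3.14 ± 0.30, adjusted p = 2.09e-13), Rflnb by 3.74 ± 0.34 and St8sia6 by 3.2 ± 0.26. Kifc3 rose by 2.23 ± 0.41, Il12rb1 by 2.07 ± 0.45 and Galk1 by 1.87 ± 0.38. Naive-state and quiescence genes were lower in 15 of 24 (15 lower and 1 higher adjusted over the list alone; median −1.18, camera adjusted p = 6.78e-17, adjusted p = 1.89e-06 with an estimated correlation), with Klf3 at −2.39 ± 0.24. Ribosome biogenesis genes were higher in 20 of 34 (28 adjusted over the list alone; median 0.76, camera adjusted p = 1.47e-15, adjusted p = 0.0268 with an estimated correlation), with Nop2 at 1.13 ± 0.19. Immediate early genes were lower in 10 of 28 (11 adjusted over the list alone; median −0.81, camera adjusted p = 9.93e-08, adjusted p = 0.15 with an estimated correlation), with Egr1 at −2.37 ± 0.26. ATF4-driven genes were higher in 7 of 24 (8 adjusted over the list alone; median 0.54, camera adjusted p = 3.02e-06, adjusted p = 0.134 with an estimated correlation), with Psat1 at 1.24 ± 0.22. In all, 650 genes were higher and 812 lower. The split was 904 and 661 in DESeq2, 936 and 671 with RLE factors, 576 and 236 spike-scaled (median of all genes 0.25) and 139 and 233 on mitochondrial mRNAs (median 0.10), and the number called was 2728 with the replicate number as a block within each cell state and 217 without replicate 4.

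Translation-dependent decay per gene was taken as the gain from cycloheximide under the transcription inhibitor at 3 h, and translation-independent decay as the loss from 0 h that remained with cycloheximide. If the pathways exclude each other, genes high in one should be low in the other. Across 10741 genes, which are not independent replicates, Spearman's rho between them was 0.059 with the first from the triptolide arm and the second from the DRB arm, and 0.087 the other way round. With harringtonine in place of cycloheximide these turn to −0.012 and −0.053. In resting cells rho was 0.147 with separate replicates for each, and 0.092 with harringtonine. Shared libraries pull rho down, as cycloheximide libraries enter with opposite sign, and gave 0.031, −0.066 and 0.123 (activated triptolide, DRB, resting). Simulated counts gave −0.41, −0.536 and −0.429 on average with no relation, but −0.128 with unrelated effects planted (rho 0.013, activated). The medians of translation-dependent decay were 0.80, 0.54 and 1.20 for proteasome subunits and 0.78, 0.63 and 1.06 for ribosome biogenesis genes (same arms). With an estimated correlation only the call of the proteasome in resting cells stood (adjusted p = 0.0272). Translation-dependent decay had a rho of 0.711 between the triptolide and DRB arms of activated cells, with 78.475% of genes on the same side, and 0.734 between activated and resting cells, with 78.242%.

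**Figure D5:**
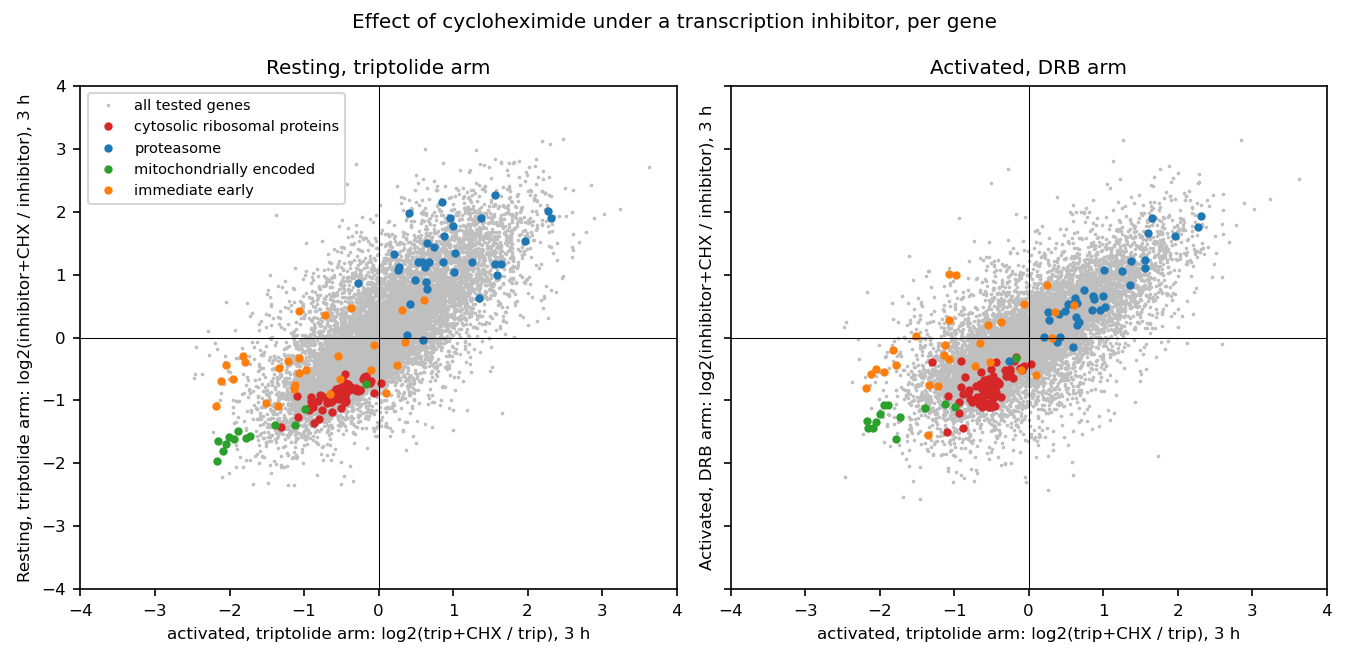
Translation-dependent decay per gene (log2, cycloheximide added against transcription inhibitor alone, 3 h), activated triptolide arm on the x axis against the resting triptolide arm (left) and the activated DRB arm (right) on the y axes, with ribosomal protein, proteasome, mitochondrially encoded and immediate early genes coloured. Spearman's rho across genes was 0.734 against the resting and 0.711 against the DRB arm. The ribosomal protein medians of −0.51, −0.87 and −0.92 (activated triptolide, DRB, resting) turn to 0.12, −0.07 and −0.02 spike-scaled.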

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

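The tests of relative scaling and of chance sharing between cell states were chosen only after the results were seen.

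Tested differences between groups were the first reason for a closer look. The 3 h triptolide change differed between activated and resting cells for 695 genes, the cycloheximide effect for 31 and the change under triptolide or DRB for 148. The other signal lay in intronic counts, which no comparison above uses. Of near-silent genes that gained reads after 3 h and had intronic counts, 90.2% rose over 1 log2 per spike-in molecule in introns after activated triptolide, 94.9% after DRB and 98.1% after resting triptolide. Among other near-silent genes, not picked for exon gains, these shares were 30.7%, 16.8% and 38.9%.

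Near-silent genes that gained reads numbered 94, 50 and 61 in the 3 arms, and 15 were shared by all. A larger share of a smaller pool of mRNA is argued against. It adds nothing per spike-in molecule. These genes, though chosen for large rises, rose by at least 1.71 spike-scaled (smallest median 3.26, floor 3 counts per group). A place in gene-dense regions is argued against. An expressed gene within 50 kb downstream on the same strand was at most 1.97 times as common as among other near-silent genes. Run-on from an expressed gene upstream on that strand is a candidate that met its test. Such a gene lay within 50 kb upstream of 59.6%, 90% and 85.2% of them, at least 3.9 times the share among other near-silent genes. These include genes the filter left out, which may inflate both ratios. Sim1 is an example, 43269 bases beyond Ascc3, with 3 intronic counts at 0 h and 2343 after 3 h. The genes without such a neighbour stay unexplained.

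Coding length went with the cycloheximide effect, at a rho across genes of -0.114 in activated triptolide, -0.065 in DRB and -0.219 in resting cells. With harringtonine in place of cycloheximide rho was -0.031, 0.101 and -0.129, so the sign turns in DRB. Without a transcription inhibitor rho with the cycloheximide effect was 0.126 in activated and -0.057 in resting cells. In equal groups of genes from the shortest to the longest the median effect was -0.02, 0.09, 0.05, -0.03 and -0.25 in activated triptolide, -0.07, 0, -0.02, -0.09 and -0.21 in DRB, with no steady trend over the shorter ones in either, and 0.2, 0.16, 0.06, -0.08 and -0.37 in resting cells. Length of the 3′ UTR had a rho of -0.193, -0.164 and -0.204 in the 3 arms, larger in size than coding length in the activated ones, and the lengths were not separated. Low counts are argued against as the cause, since rho was -0.121, -0.075 and -0.239 among genes with at least 10 CPM. For 0 h libraries of the inhibitors against untreated ones rho was 0.066 (activated triptolide), 0.028 (DRB) and 0.005 (resting). The first is over 0.5 of the size of the effect in its arm, though of opposite sign, and the last is far below it. A length bias between libraries cannot be told apart, because 0 h libraries do not measure a bias in the 3 h ones. A biological effect of coding length stays open and untested.

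Genes that differ between cycloheximide and harringtonine under triptolide were shared between states 21 times as often as independent lists would be, which argues against chance differences between sets of libraries. Without triptolide, 85.9% of those called in activated cells and 91.4% of those called in resting cells had the same direction, which argues against a difference made only where triptolide is present. What the inhibitors do differently to these messages was not tested.

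Other groupings of the same libraries were fitted on those libraries alone. For 3 against 3 there are 10 groupings, too few for a share under 0.05, and in each of the 14 such comparisons 1 of 10, the real one, called as many genes. The real and highest other counts were 2671 and 0 for activation, 4360 and 0 for activated triptolide, 2700 and 0 for DRB, 5713 and 0 for resting triptolide and 946 and 0 for untreated time. With cycloheximide added they were 2451 and 0, 459 and 0, and 3541 and 0, and with harringtonine added 2254 and 0, and 2460 and 0. Cycloheximide against harringtonine gave 208 and 1 in activated and 67 and 2 in resting cells, and cycloheximide alone 2814 and 0, and 3166 and 0. For the differences 100 groupings were drawn. As many genes as the real one came from 3 for triptolide decay by state (405, highest other 4939), 4 for the cycloheximide effect (1, highest other 2942) and 3 for triptolide against DRB (53, highest other 3380). These shares are under 0.05, but the groupings that call several times the real count point to a structure of the samples, cell state and treatment, that they separate, and a real count of 1 gives little to weigh.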

How the results depend on the processing

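Spike-in scaling, the block within each cell state, coding-sequence counts, spike-in scaling with replicates left out, sign flips within replicate numbers and the settings without the shallowest libraries or activated 3 h triptolide replicate 3 were chosen only after the data were seen. Except where a cause is given, the cause was not tested.

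Of 82 described list results, 82 kept their call with DESeq2, RLE factors, no filter, only the libraries compared, either block, without replicate 2, and without the shallowest libraries. The call ended for 1 without replicate 3, for 2 without replicate 4 and for 2 with coding-sequence counts. With an estimated correlation, which widens the error of large lists, 18 of the 82 kept their call and 64 did not, and 25 calls were made among all lists and main comparisons. Of 501 named gene values, 486 kept direction and call with RLE factors, 479 with no filter, 494 without the shallowest libraries and 480 without activated 3 h triptolide replicate 3. The number was 459 of 472 with DESeq2, 443 of 487 with only the libraries compared and 442 of 486 with coding-sequence counts. Leaving out replicates 2, 3 and 4 ended 59, 38 and 98 calls. The value of Ltb on activation, which was not called, went to -0.82 with the block within each state.

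Scaled on mitochondrial mRNAs, the number of genes called became 8787 for activated triptolide, 8544 for DRB, 7178, 5966 and 7082 with cycloheximide added (activated triptolide, DRB, resting triptolide), 4886 and 5491 with harringtonine added (activated, resting), 8865 for cycloheximide alone in resting cells and 372 for untreated time. For the differences it became 1.1e2 to 2 digits (triptolide by state, 16 higher and 89 lower), 1 (cycloheximide effect) and 70 (triptolide against DRB). Scaled on spike-ins it became 1530 for activation, 8590 for activated triptolide, 8586 for DRB, 3173 for DRB with cycloheximide, 6595 for cycloheximide alone in resting cells and 812 for untreated time, and 208, 0 and 63 for these differences. The count of 0 in edgeR stands beside 724 genes at an unadjusted p under 0.05, and DESeq2 with its own factors called 53. These scalings shift the median and also change the spread: the SE of Egr1 on activation was 0.32, and 0.48 on spike-ins. What each adds to the change in number was not separated.

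With the replicate number as a block within each state, the number called became 4881 for activation, 4518 and 3443 with cycloheximide added in activated cells (triptolide, DRB), 4017 and 4056 with harringtonine added (activated, resting), 1216 and 676 for cycloheximide against harringtonine (activated, resting), 4706 for cycloheximide alone in resting cells and 2728 for untreated time. For the differences it became 1762, 314 and 323. A block over both states gave 104 for the cycloheximide difference and moved no other of these counts by over 1.5 times. Untreated time in resting cells went from 686 to 1104 with that block and to 1988 with the block within each state.

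With only the libraries compared, so fewer libraries to estimate the spread, the number was 2700 for DRB, 459 for DRB with cycloheximide, 208 and 67 for cycloheximide against harringtonine (activated, resting), 946 for untreated time, and 405, 1 and 53 for the differences. Library size alone gave 394 for cycloheximide against harringtonine in resting cells and 122 for the cycloheximide difference. Coding-sequence counts gave 148 for the former and 439, 12 and 73 for the differences. For the cycloheximide difference no filter gave 18.

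Leaving out each replicate in turn gave 1107 to 2952 genes for activation, 2347 to 3762 for DRB, 1261 to 2364 for activated triptolide with cycloheximide, 572 to 1885 for DRB with cycloheximide and 1737 to 2979 for resting triptolide with cycloheximide. With harringtonine added it gave 1318 to 2076 in activated and 1060 to 2115 in resting cells, and for cycloheximide against harringtonine 87 to 413 and 44 to 136. It gave 1566 to 2941 for cycloheximide alone in activated and 884 to 2338 in resting cells, 217 to 1306 for untreated time, and 146 to 478, 1 to 22 and 31 to 133 for the differences. Without activated 3 h triptolide replicate 3 the number was 4289 for DRB, 2471 and 3694 with cycloheximide added to triptolide (activated, resting), 2316 and 2529 with harringtonine added, 502 and 231 for cycloheximide against harringtonine, 3276 and 2870 for cycloheximide alone, 614 for triptolide by state and 1429 for untreated time. The lowest came without replicate 4 in each of these but activation, where it came without replicate 2. Fewer libraries leave less power, which does not account for the gap between replicates.

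Spearman's rho between the translation-dependent and translation-independent measures ranged from 0.028 to 0.102 (first from triptolide), 0.062 to 0.109 (first from DRB) and 0.117 to 0.149 (resting) with replicates left out in turn. With harringtonine in place of cycloheximide it became -0.012, -0.053 and 0.092. Spearman's rho of the translation-dependent measure between arms ranged from 0.6 to 0.679 against DRB and from 0.666 to 0.699 against resting cells, and the share on the same side from 73.95 to 77.423% and from 75.552 to 76.808%. Among genes with at least 10 CPM these were 0.823 and 0.819, and 82.903 and 82.197%. With harringtonine the values against resting cells were 0.686 and 76.12%.

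The spike-scaled median of mitochondrially encoded mRNAs went from 0.81 to -0.58 without replicate 3 and -0.37 without activated 3 h triptolide replicate 3 in activated triptolide, and from -0.08 to 0.14 and 0.06 without replicates 3 and 4 in DRB. For ribosomal protein genes with cycloheximide added it went from -0.07 to 0.11 without replicate 2 in DRB and from -0.02 to 0.01 without replicate 3 in resting cells.

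Of 100 simulated 2-fold changes 30 were recovered between groups and 10 in differences, so an uncalled gene is not shown to be unchanged.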

Other observations

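The levels of marker genes below were read without a test chosen in advance for single genes.

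The 0 h libraries of each inhibitor were compared with untreated 0 h libraries, as a background for the time courses. In activated cells immediate early genes were already lower in 9 of 28 with triptolide (median -1.11) and in 10 of 28 with DRB (median -1.19). In resting cells their median was -0.21. For the genes called, changes from 0 h in activated cells start below the level of untreated cells. The list was not tested as a whole. Exon counts per ERCC count at 0 h were 106% of the untreated level with triptolide (exact p = 0.8) and 95.4% with DRB (exact p = 0.5) in activated cells, and 98.1% with triptolide in resting cells (exact p = 0.9).

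By introns, after 3 h of triptolide the log2 ratio of intron to exon counts changed by -0.56 in activated (exact p = 0.2) and -0.35 in resting cells (exact p = 0.1), and by -0.40 after DRB (exact p = 0.3). With cycloheximide alone it changed by -0.55 in activated (exact p = 0.2) and -1.06 in resting cells (exact p = 0.1).

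Among marker genes of other blood cells Igkc, of the B cell list, was not low: it averaged 207 CPM over the groups and was highest in resting 3 h triptolide (821 CPM), and where its reads come from was not tested. Others of these lists stood lower: Cd74 averaged 33.3 CPM, Cd79a 1.46 CPM, Lyz2 0.407 CPM, Cd8a 0.87 CPM and Hbb-bs 3.28 CPM.

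A hypothesis that coding length goes with translation-dependent and translation-independent decay in opposite directions was tested, and opposite signs of rho across genes were seen in 0 of 3 arms. Spearman's rho with translation-independent decay was -0.098, -0.058 and -0.235 in the activated triptolide, DRB and resting arms, of the same sign as with translation-dependent decay. Among genes with at least 10 CPM it was -0.060, -0.018 and -0.231. With harringtonine in place of cycloheximide rho with translation-dependent decay in DRB was 0.101.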
